A study of Mus musculus with 16 samples.

How the data were processed

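Values were log2 expression per probe set on a one-colour Affymetrix mouse gene array, deposited by the authors as 1 column per array for 16 arrays and 30177 probe sets. They were made with RMA, per the submitters' processing notes; RMA corrects background, quantile-normalizes probes over arrays and summarises each probe set. Its version, the software and which arrays were normalized together are not given in the sources used here, and the values carry no detection calls. Scale was checked from the values, which ran from 1.036 to 13.84 with array medians of 4.79 to 4.93. Because RMA equalises the distributions, a change in total RNA per cell leaves no trace, and the direction of small shifts depends on the scaling. Biotin-labelled total RNA was hybridised, per the labels.

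Groups and replicate numbers came from the sample titles. The arrays formed 7 groups, with 2 arrays each except the 2 naive LPM groups with 3. Of the probe sets 21789 had 1 gene symbol, 1621 several and 6767 none here; the last 2 kinds were not named or tested. Of the first kind 21698 matched the reference gene table (GRCm38.p6) by Entrez ID, and 0 symbols changed. Positions are those of the genes in that table. For 999 of 19938 genes with more than 1 probe set, the one with the highest mean was used. A gene was tested if its signal exceeded the array median on at least 2 arrays, which kept 11634 genes and left out 8304. Cdkn1a and other genes without a probe set of a single symbol were not analysed here.

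Differences were fitted in R 4.3.3 with limma 3.58.1 (lmFit, eBayes) as group means over all 16 arrays, which share 1 variance estimate (9 residual and 6.61 prior degrees of freedom, median within-group SD 0.171). Benjamini-Hochberg adjusted p under 0.05 was taken within each of 10 comparisons, each over 11634 genes. An interaction is the KO minus WT difference in 1 set minus that in another. Of 29 gene lists fixed before the data were examined, 26 had at least 3 tested genes and were tested with camera, preset correlation 0.01, adjusted over the lists of a comparison; each test was repeated with an estimated correlation, under which the MHC class II list in AM and the 2 identity lists between LPM and AM kept their calls and all other list calls were lost. Named genes followed a rule set before the data were examined. It covers, where measured, a fixed set that includes Bhlhe40, Bhlhe41, Maf, Myc, Klf2, Klf4, Gata6, Mki67, Ccnd1, Ccnd2 and Cdkn1a. To these it adds the 8 largest called rises and falls without overlap between arrays (5 each for interactions), and the most changed members of each list. Predicted or numbered symbols were left out. The fixed set is not printed in full for every comparison. Klf4 in both IL-4c responses, and Bhlhe41, Maf and Mki67 in that of KO, were called but are not given below. The same holds for Maf, Myc, Klf2, Klf4, Ccnd1 and Ccnd2 between LPM and AM. Correlations and overlaps of comparisons with the same WT arrays were set beside 100 simulations of unchanged groups.

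The fit was tested on simulated data with the 11634 genes' means and variances, 200 of them changed, in 20 runs. For KO against WT in naive LPM it recovered 60.1% of genes changed 1.5-fold and 98.1% of genes changed 2-fold. For AM these shares were 32.5% and 90.5%, for KO in IL-4c LPM 31.7% and 91.6%, and for LysM 30.9% and 89.9%. False calls made up 4.9% to 5.3% of calls, where 20 further genes changed 1.5-fold were counted as true. The simulated genes were normal and independent of each other, so this share does not measure false calls on the real arrays.

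Alternatives planned before the data were examined were a second quantile normalization, centring on the array median, no dim filter or one set at the 95th percentile of 1035 olfactory receptor probe sets, the mean of a gene's probe sets, an intensity trend with robust variance, only the compared arrays, a replicate block, array weights and leaving out each array. Leaving out an array of a pair leaves 1, assumed to vary like the other groups. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No count of reads applies to arrays.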

Results

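Gene expression was measured in macrophages sorted from male C57BL/6 mice on 16 one-colour Affymetrix mouse gene arrays. The series compares mice with and without Bhlhe40, a basic helix-loop-helix transcriptional repressor. Alveolar macrophages (AM), the resident macrophages of the airspaces, came from lung digests of untreated mice, with 2 wild-type (WT) and 2 knockout (KO) arrays. Large peritoneal macrophages (LPM), the main resident macrophages of the peritoneal cavity, came from lavage of untreated mice, with 3 WT and 3 KO arrays. A further 6 LPM arrays came from mice injected on days 0 and 2 with IL-4c, which drives alternative activation and local division of resident macrophages, and killed on day 4. They comprised 2 WT arrays, 2 KO arrays and 2 arrays labelled Bhlhe40LysM, the series' name for LysM-Cre with a floxed Bhlhe40 gene. Median log2 signal lay between 4.79 and 4.93 on the 16 arrays. Replicate arrays of a group correlated at 0.989 to 0.995 (Pearson, across probe sets, which are not independent replicates), and naive LPM correlated with AM at 0.939 to 0.945. Of 19938 genes with a named probe set, 11634 were tested. The labels do not say whether replicates were separate mice or pools, so p-values measure the spread between these arrays, and the number of arrays limits the precision. Signed values are log2 differences, first group minus second, with the standard error and adjusted p from limma.

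Bhlhe40 itself (Entrez 20893, chromosome 6, 108660629 to 108666925, GRCm38.p6) was read by 1 probe set. In AM its log2 signal was 9.57 and 10.07 in WT and 7.53 and 7.75 in KO, 4.51-fold lower in KO (log2 difference -2.17 ± 0.19 SE, adjusted p = 6.1e-05). In naive LPM it was 8.66, 8.75 and 8.64 in WT and 6.79, 6.5 and 7.11 in KO, 3.7-fold lower (-1.89 ± 0.15, adjusted p = 6.4e-06). In IL-4c LPM the KO arrays, at 8.01 and 7.9, lay closer to the WT arrays, at 8.77 and 8.99 (-0.93 ± 0.19, adjusted p = 0.013). The arrays labelled Bhlhe40LysM read 8.75 and 8.83, and their difference from WT was -0.09 (95% interval -0.5 to 0.31, adjusted p = 0.84). Where the probes lie relative to the deleted part of the gene is not given in the sources used here, so the unlowered signal neither checks nor contradicts the deletion, and directions drawn from these 2 arrays rest on their label.

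**Figure D1:**
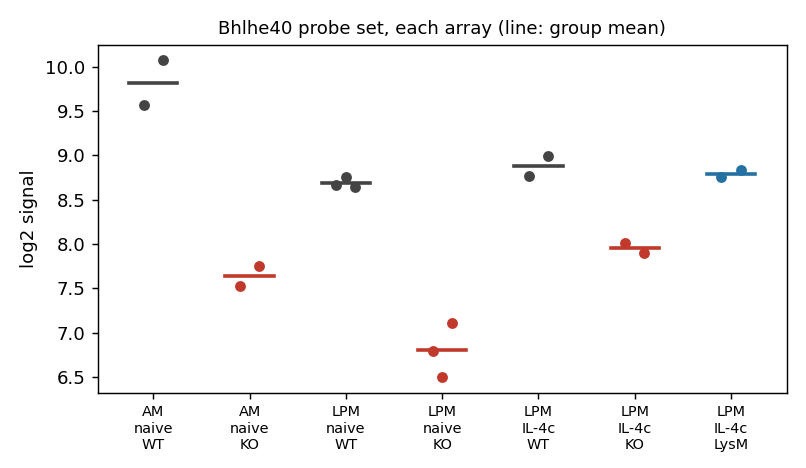
Log2 signal of the Bhlhe40 probe set on each array (points) by group, with the group mean as a line; the axis does not start at 0. The KO arrays read lower than the WT arrays of the same cells in every set, and the 2 arrays labelled Bhlhe40LysM, at 8.75 and 8.83, lie at the level of the IL-4c WT arrays.

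The first comparison asked what the loss of Bhlhe40 changes in resting AM. MHC class II genes, which present antigen to CD4 T cells, were lower in KO AM: H2-Eb1 fell by 1.57 on the log2 scale (SE 0.17, adjusted p = 0.00033), Cd74, the invariant chain, by 1.39, H2-Ab1 by 1.38 and H2-Aa by 1.23. Of the 8 members tested, 4 fell (6 when adjusted over the list alone) and 0 lay above 0, with a median of -0.927 (camera adjusted p = 1.64e-22; adjusted p = 0.00262 with an estimated correlation). Hpgds, a prostaglandin D synthase, was 4.65-fold higher (2.22 ± 0.33, adjusted p = 0.0067) and Cd93 3.49-fold higher (1.80 ± 0.17, adjusted p = 0.00011), and Tnfsf18 (1.43), the G-CSF receptor gene Csf3r (1.28), Gpr141 (1.24) and Osbpl3 (0.83) also rose. Mfsd6 fell by 1.32, Spag11b by 1.22 and Ereg by 1.20. In all, 14 genes passed the threshold, 6 higher and 8 lower, Bhlhe40 among the latter.

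Markers of other cell types say little about whether fewer antigen-presenting cells were sorted from KO lungs. Markers of small peritoneal macrophages, monocytes and dendritic cells (median difference 0.029) and of B cells (-0.011) averaged 4.2 and 4.67 in WT AM, below the array medians, where a loss would not show. Of 9 tested dendritic cell markers, chosen after the MHC class II result was seen, 0 were called, and they went both ways: Ccr7 (-0.30), Ccl22 (-0.29) and Ccl17 (-0.26) lay below 0 and Plbd1 (0.49), Naaa (0.36) and Clec9a (0.27) above it. T and NK cell markers had a median of -0.225, with 1 of 5 above 0 (camera adjusted p = 0.0936), and mast cell markers a median of -0.194 (adjusted p = 0.224). Of 5 neutrophil markers 1 rose, Csf3r, and 2 when adjusted over the list alone. The cell cycle lists held no called gene (medians 0.083 for DNA replication and S phase and 0.014 for G2/M and mitosis), and of 26 lists the only other call was the Maf-associated list, lower at adjusted p = 0.00874, with adjusted p = 0.832 under an estimated correlation. Without 1 array at a time the number of called genes ran from 8 (without KO replicate 2) to 19 (without WT replicate 2), and 9 genes were called without KO replicate 1. At an unadjusted p under 0.05 there were 620 genes against 582 expected by chance.

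In naive LPM 62 genes were higher and 157 lower in KO. Stab1, a scavenger receptor, was 9.95-fold higher (3.31 ± 0.18, adjusted p = 5.7e-08), and Lyve1, the hyaluronan receptor, 4.58-fold higher (2.19 ± 0.31, adjusted p = 0.0016). Rcn3 (2.00), Tlr1 (1.79), the folate receptor gene Folr2 (1.73), F13a1 (1.68), Cd28 (1.66) and Mrvi1 (1.59) completed the largest rises. Pglyrp1, a peptidoglycan recognition protein, was 5.98-fold lower (-2.58 ± 0.31, adjusted p = 3e-04). Lrg1 fell by 2.30, Prtn3, a serine protease of granules, by 1.91, Emb by 1.91, Stard13 by 1.88, the histidine decarboxylase gene Hdc by 1.86 and Chil3 by 1.76. Of the paralog and the other regulators fixed for every comparison, Bhlhe41 rose by 1.57 (SE 0.31, adjusted p = 0.016). In WT both Bhlhe41 (3.84 to 4.73) and Cd28 (4.37 to 4.74) lay below the array medians, so the size of these rises is not exact. The same holds for falls that end below the array medians in KO.

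Of 20 tested genes of the Maf-associated resident macrophage list, 6 rose and 0 fell (9 and 1 adjusted over the list alone; median 0.216; camera adjusted p = 4.65e-08; adjusted p = 0.367 with an estimated correlation). The large peritoneal macrophage identity list moved down, with 2 of 25 called (median -0.203; camera adjusted p = 0.00252; adjusted p = 0.286 with an estimated correlation). Markers of other cells went both ways: 7 of 9 lay above 0 for small peritoneal macrophages, monocytes and dendritic cells (median 0.389, camera adjusted p = 0.0707) and 5 of 5 for T and NK cells (median 0.189, adjusted p = 0.0586), but 1 of 5 for neutrophils (median -0.135, adjusted p = 0.359) and 1 of 3 for eosinophils (median -0.032), and of 3 mast cell markers 1 fell (mean -0.544, adjusted p = 0.367). Other cells in the KO sorts were not excluded as a source of these shifts. Of 31 genes of alternative activation 2 rose and 2 fell, Arg1 (1.46) among the former and Irf4 (-0.61) among the latter, and the list as a whole was not called (adjusted p = 0.236). The immediate early and dissociation stress list was lower (median -0.317; camera adjusted p = 0.0432; adjusted p = 0.486 with an estimated correlation). Neither cell cycle list held a called gene (medians 0.03 and -0.089), but the KO arrays were split: G2/M genes averaged 5.413, 5.418 and 6.167 on KO replicates 1 to 3, against 5.722 to 5.739 in WT, and S phase genes 5.619, 5.587 and 5.993, against 5.619 to 5.766. Maf, Myc, Gata6, Klf2, Klf4, Ccnd1, Ccnd2 and Mki67 were not called, with differences from -0.4 to 0.85. In all, 219 genes passed, 62 higher and 157 lower.

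That split depends on scaling: 45.6% of called genes were higher after quantile normalization was applied again and 44% after each array was centred on its median, against 28.3% as deposited. Leaving out 1 array gave between 75 genes (without WT replicate 1) and 163 (without KO replicate 3), with 82, 105, 104 and 96 without WT replicates 2 and 3 and KO replicates 1 and 2, and array weights gave 419.

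The effect of genotype differed between the cell types for 29 genes, 9 with a higher difference in LPM and 20 with a lower one. Stab1 (difference of differences 3.76 ± 0.28, adjusted p = 7.6e-06), Tlr1 (1.97), Rcn3 (1.81), Tmc3 (1.60) and Arg1 (1.58) had the higher KO effect in LPM, as did the MHC class II genes H2-Eb1 (1.67), H2-Ab1 (1.18) and H2-Oa (1.05). Cd93 (-1.92), Stard13 (-1.98), Csf3r (-2.13), Lrg1 (-2.28) and Pglyrp1 (-2.51) had the lower one. As lists, MHC class II (6 of 8 genes above 0, 3 called, median 0.989) and the Maf-associated genes (16 of 20 above 0, 1 called, median 0.449) moved up and LPM identity (5 of 25 above 0, 1 called lower, median -0.323) down, with estimated-correlation adjusted p of 0.0827, 0.223 and 0.223. The MHC class II value comes from the fall in AM, as the list had a median of -0.207 in naive LPM and was not called there. Csf3r rose in KO AM and fell in KO LPM (-0.85, adjusted p = 0.011). Across genes the AM and naive LPM differences correlated at r = -0.096 (rho = -0.174), and 1 gene was called higher and 2 were called lower in both, against 0.032 and 0.11 expected for independent lists; of the latter 2, Bhlhe40 is the deleted gene and Mfsd6 the other. The cell type interaction is also a comparison of separate sorts, with 4 and 6 arrays. Centring each array on its median raised the share of positive calls from 31% to 58.3% and moved the median of all genes from -0.09 to 0.047. Without single arrays the count ran from 9 (without AM KO replicate 2) to 57 (without AM WT replicate 2), with 15 without AM WT replicate 1, 18 without AM KO replicate 1, 19 and 16 without LPM WT replicates 1 and 2, and 16 without LPM KO replicate 2.

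IL-4c changed LPM of both genotypes broadly. In WT, Rnase2a rose 336-fold (8.39 ± 0.18, adjusted p = 3.5e-14), AA467197 by 7.66, the lectin Mgl2 by 6.10, Cst7 by 5.75, the chitinase-like genes Chil3 by 5.66 and Chil4 by 5.50, Timd2 by 5.44 and the uncoupling protein Ucp1 by 5.07. Most of these lay below the array medians in naive WT (Rnase2a 2.65 to 3.15, AA467197 3.28 to 3.44, Cst7 3.95 to 4.36, Chil4 3.23 to 3.58), so the size of their rise is limited by background and not exact. Cxcl13 fell by 5.32, Cxcl2 by 4.52, Ccl3 by 4.52, Rgs2 by 4.32, F13a1 by 4.12, Rgs1 by 4.07, Pilra by 3.89 and Clec4d by 3.87. Where such a fall ends below the array medians, its size and rank are limited by background too. All 38 tested genes of DNA replication and S phase and all 38 of G2/M and mitosis rose, with medians of 1.66 and 2.136 (camera adjusted p = 1.07e-21 and 3.61e-23; adjusted p = 0.11 and 0.236 with an estimated correlation). Examples were Rrm2 (4.10), Plk1 (2.74), Tyms (2.72), Cdk1 (2.67) and Mki67 (1.77). Of 31 genes of alternative activation 18 rose and 4 fell (median 0.829; camera adjusted p = 9.46e-06; adjusted p = 0.0701 with an estimated correlation). Oxidative phosphorylation (21 of 23 higher, 1 lower), cholesterol synthesis (11 of 17 higher), glycolysis (9 of 14 higher, 2 lower) and ribosome biogenesis (9 of 23 higher, 2 lower) also moved up, with estimated-correlation adjusted p of 0.268, 0.313, 0.268 and 0.625. The identity list (13 of 25 lower, 2 higher), immediate early genes (11 of 17 lower, Dusp1 -3.30), complement and phagocytic receptors (11 of 19 lower, 3 higher) and chemokines (8 of 18 lower, 3 higher) moved down, with estimated-correlation adjusted p of 0.0701, 0.0701, 0.173 and 0.478. B-cell markers were lower in both genotypes, 6 of 8 in each (medians -0.953 and -0.978; adjusted p = 0.268 and 0.254 with an estimated correlation).

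In KO the same treatment raised Rnase2a by 8.44, Chil3 by 7.47, AA467197 by 7.19, Chil4 by 5.77, Mgl2 by 5.56, Klk9 by 5.16, Cst7 by 5.13 and Timp1 by 4.78, with the same limit from background (naive KO arrays read 3.06 to 3.69 for AA467197, 3.08 to 3.58 for Chil4 and 3.81 to 6.09 for Chil3). It lowered Pilra by 5.30, F13a1 by 5.12, Rgs2 by 3.73 and Cxcl13 by 3.67, with the same limit where a fall ends below the array medians. In KO 31 of 38 S phase genes and all 38 G2/M genes rose, with medians of 1.025 and 1.491 (camera adjusted p = 5.59e-12 and 8.24e-18; adjusted p = 0.254 for both with an estimated correlation). Oxidative phosphorylation (20 of 23 higher), cholesterol synthesis (13 of 17 higher), glycolysis (9 of 14 higher, 1 lower) and genes of alternative activation (16 of 31 higher, 3 lower) moved up, and immediate early genes (10 of 17 lower) and LPM identity (10 of 25 lower, 4 higher) down. Estimated-correlation adjusted p was 0.0861 for alternative activation and 0.254 for the others. Bhlhe40 rose by 1.16 in KO (adjusted p = 0.00011) and differed by 0.20 in WT (adjusted p = 0.39), with a difference of differences of 0.96 (adjusted p = 0.089). In all, 4788 genes passed in WT (2560 higher, 2228 lower) and 4342 in KO (2552 higher, 1790 lower). Of 704 genes raised at least 2-fold in WT, 645 (91.6%) were also called higher in KO, with median differences of 1.42 and 1.11; of 560 lowered, 483 (86.2%) were also called lower, with medians of -1.34 and -0.99. These genes were chosen on WT, which enlarges the WT value. The highest value of an array was 13.67 to 13.84 on the IL-4c arrays and 13.15 to 13.33 on all others. No label gives a processing batch. If the naive and IL-4c arrays were processed apart, the design does not separate the treatment from that batch, for small differences above all. The share of called genes that were higher was 53.5% in WT and 58.8% in KO as deposited, and 44.2% and 46.5% with arrays centred on their medians, and without IL-4c KO replicate 1 there were 2787 calls.

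Among IL-4c LPM, a number of cell cycle genes fell and single genes such as Plac8, Ccl7 and Ccl2 rose in KO against WT. All 38 tested S phase genes lay below WT, with 9 called (32 adjusted over the list alone), among them Rrm2 (-1.37 ± 0.31, adjusted p = 0.021), E2f8 (-1.07), Gins1 (-1.03) and Uhrf1 (-0.96). The median was -0.695 (camera adjusted p = 1.75e-20; adjusted p = 0.163 with an estimated correlation). All 38 G2/M genes lay below WT too, with 3 called, Aurka (-0.95), Kif4 (-0.88) and Ect2 (-0.87), and 17 adjusted over the list alone (median -0.645; camera adjusted p = 3.17e-14; adjusted p = 0.348 with an estimated correlation). Mki67 differed by -0.51 (adjusted p = 0.42). Plac8 was 39.5-fold higher in KO (5.31 ± 0.56, adjusted p = 6.4e-05), Ccl7 and Ccl2, ligands of the monocyte receptor CCR2, rose by 3.77 and 3.38, Rcn3 by 3.48, Stab1 by 3.43, the nucleotide receptor P2ry6 by 2.78, Tnxb by 2.71 and Anxa5 by 2.36. Ly6a2 was 18-fold lower (-4.17 ± 0.44, adjusted p = 6.4e-05), Ucp1 fell by 3.15, Timd2 by 2.87, Pglyrp1 by 2.73, Mall by 2.71, Parm1 by 2.22, Id2 by 1.96 and the malic enzyme Me1 by 1.74.

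The Maf-associated list had 9 of 20 genes higher and 0 lower, with Folr2 at 1.85, Cd163 at 1.38 and Maf at 0.73 (median 0.691; camera adjusted p = 2.97e-12; adjusted p = 0.163 with an estimated correlation). LXR targets (2 of 10 higher, median 0.764), interferon-stimulated genes (1 of 17, median 0.521), complement and phagocytic receptors (1 of 19, median 0.247), chemokines and cytokines (3 of 18 higher, 1 lower), circadian clock genes (1 of 14) and immediate early genes (4 of 17) had a camera call upward, with estimated-correlation adjusted p of 0.269, 0.348, 0.163, 0.348, 0.304 and 0.348. The KO arrays were uneven. Chemokines and cytokines averaged 7.004 and 6.057 on KO replicates 1 and 2, against 5.992 and 5.698 in WT. Immediate early genes averaged 7.779 and 7.499 on the same KO arrays, against 7.422 and 7.427 in WT. Ribosome biogenesis was lower (0 of 23 called, median -0.246; adjusted p = 0.398 with an estimated correlation). Neutrophil markers (1 of 5 higher, the gene Csf3r) and eosinophil markers (1 of 3 lower) were called as well, with estimated-correlation adjusted p of 0.304 for both. Genes of alternative activation were not called as a list (adjusted p = 0.283). In all, 422 genes passed, 247 higher and 175 lower. The count depends on single arrays: it was 84 without WT replicate 2 and 135 without KO replicate 1, and 117 with only the 4 arrays compared. Without WT replicate 2 the S phase median was -0.5 and the G2/M median -0.56.

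**Figure D2:**
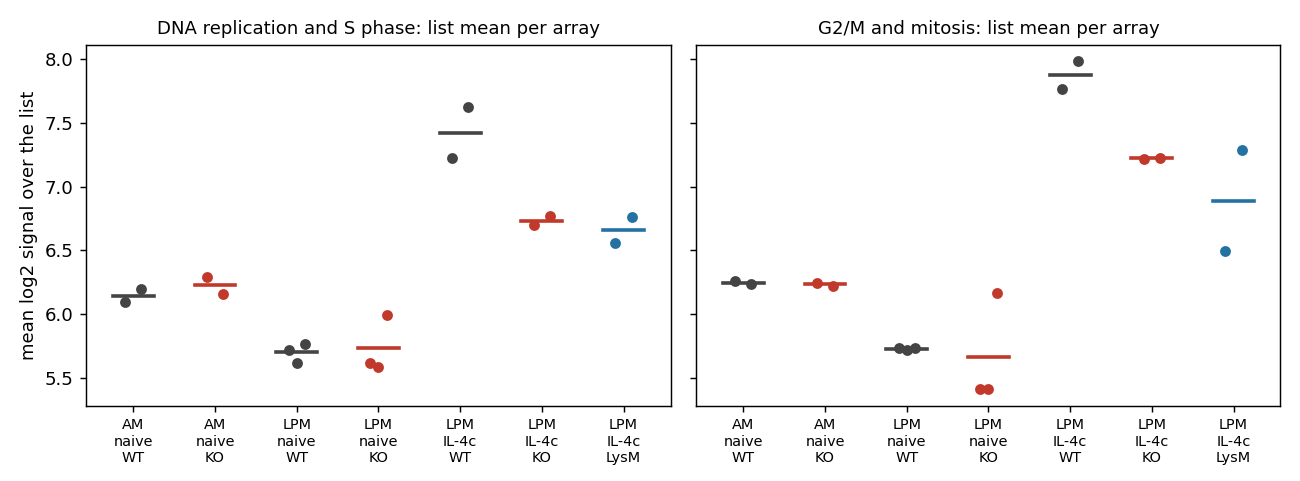
Mean log2 signal over 38 DNA replication and S phase genes (left) and 38 G2/M and mitosis genes (right) on each array (points), with the group mean as a line; the axis does not start at 0. WT IL-4c arrays average 7.42 (S phase) and 7.87 (G2/M), KO IL-4c arrays 6.73 and 7.22, and arrays labelled Bhlhe40LysM 6.66 and 6.89, above the naive LPM groups.

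The arrays labelled Bhlhe40LysM were set against the same WT arrays, to ask what deletion in myeloid cells changes. All S phase and G2/M genes lay below WT, with 24 of 38 and 26 of 38 called (35 and 38 adjusted over the list alone), medians of -0.756 and -1.006, and Rrm2 at -1.37, Bub1 at -1.34, Melk at -1.27 and Mki67 at -1.21 (adjusted p = 0.019). Camera adjusted p was 1.62e-19 and 3.12e-22, with adjusted p = 0.281 for both under an estimated correlation. The G2/M median was -0.59 without Bhlhe40LysM replicate 1 and -1.39 without replicate 2. Ccl7 rose by 4.55, Ccl2 by 4.43, Plac8 by 4.36, Stab1 by 3.52, Ccl8 by 3.49, Olr1 by 3.28, P2ry6 by 3.25 and Gpnmb by 3.15. Timd2 fell by 4.19, Ucp1 by 3.59, Pglyrp1 by 3.42, Ly6a2 by 3.03, Mall by 2.42, Sla by 2.23, Pilrb2 by 2.07 and Id2 by 2.05, and Myc by 0.78 (adjusted p = 0.033). Of the other genes fixed for every comparison, the cyclin gene Ccnd2 also differed (adjusted p under 0.05). Bhlhe40, Bhlhe41, Ccnd1, Gata6, Klf2, Klf4 and Maf were not called, with differences from -0.09 to 1.22. Interferon-stimulated genes had 9 of 17 members higher, Irf7 at 2.15 (median 0.815), and the Maf-associated list 8 of 20 higher and 1 lower, each with adjusted p = 0.281 under an estimated correlation. Genes of alternative activation were called higher here (10 of 31 higher, 3 lower, camera adjusted p = 0.0347), as were AM identity (5 of 27), LXR targets (3 of 10), complement and phagocytic receptors (5 of 19), immediate early genes (5 of 17) and chemokines (6 of 18 higher, 1 lower), with estimated-correlation adjusted p of 0.281 for the first 5 and 0.338 for chemokines. Ribosome biogenesis and oxidative phosphorylation were lower (1 of 23 and 0 of 23 called), at 0.567 and 0.338. No marker list of other cells had a camera call. Neutrophil markers (4 of 5 above 0, 1 called higher) and eosinophil markers (0 of 3 above 0, 1 called lower) had camera adjusted p = 0.0566 each. Markers of small peritoneal macrophages, monocytes and dendritic cells had 2 called higher and 1 lower (camera adjusted p = 0.257). Other cells in these sorts were not excluded. In all, 1009 genes passed, 559 higher and 450 lower, with 240 without WT replicate 2, 303 without Bhlhe40LysM replicate 1, and 150 with only the 4 arrays compared.

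The 2 mutants changed the same genes to a large extent. In both, 202 genes were called higher and 120 lower, against 12 and 6.8 expected for independent lists. The differences correlated at r = 0.803 across genes, where unchanged groups simulated against the same WT arrays gave 0.502, and the covariance was 0.113 against 0.018 simulated. Simulation gave 0.02 shared calls on average, with each gene drawn independently of the others. Genes of the data are correlated (estimated at 0.773 within the G2/M list), so that number may be too low. With 1 WT array given to each mutant, the covariance was 0.092 and 0.095 in the 2 ways of doing so (r = 0.593 and 0.595), where no control array was shared. For the values with shared controls, part of the excess may come from those controls. The naive KO comparison uses other arrays: 32 of its 62 higher genes and 14 of its 157 lower genes were also called in that direction in IL-4c KO, against 1.3 and 2.4 expected. Set directly against each other, KO and LysM arrays differed in 2 genes, both lower in KO, Pla2g7 (-1.22, adjusted p = 0.02) and G530011O06Rik (-1.785, adjusted p = 0.00293, named outside the rule after its value was seen, as the count is small), while 1024 genes had an unadjusted p under 0.05 against 582 expected. That count was 0 with only the 4 arrays compared, 8 with an intensity trend and robust variance, 46 without KO replicate 1 and 111 without LysM replicate 2. By camera the G2/M list was higher in KO than in LysM (median 0.312, adjusted p = 3.2e-07) and interferon-stimulated genes lower (median -0.451, adjusted p = 0.00041), with adjusted p = 0.941 for each under an estimated correlation. Without Bhlhe40LysM replicate 1 the G2/M direction turned (adjusted p = 0.73); G2/M genes averaged 6.493 and 7.285 on the 2 LysM arrays and 7.217 and 7.224 on the KO arrays.

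**Figure D3:**
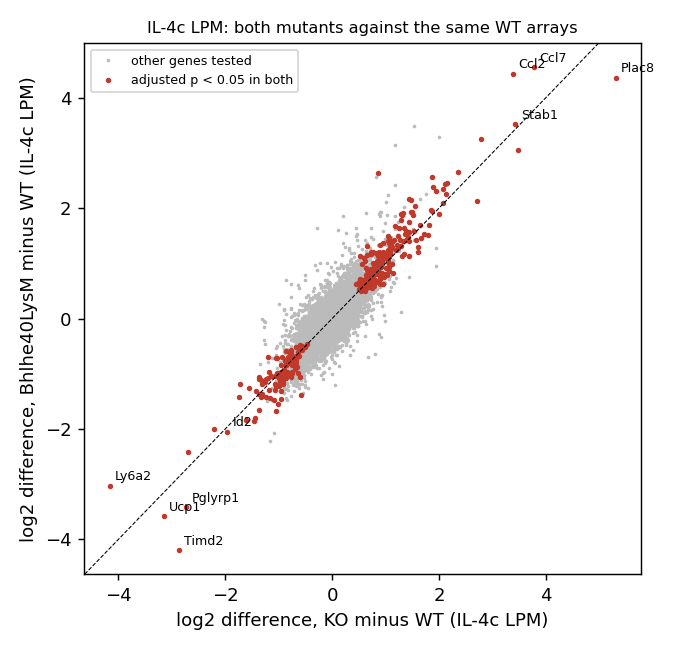
Log2 difference from the 2 WT IL-4c arrays across 11634 genes, KO on the horizontal axis and arrays labelled Bhlhe40LysM on the vertical axis, with genes called in both in red and equality as a dashed line. The 322 genes called in both in 1 direction lie along the diagonal, Plac8, Ccl2, Ccl7 and Stab1 at the upper end and Timd2, Ucp1, Pglyrp1 and Ly6a2 at the lower end; both axes share the same WT arrays.

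The genotype effect itself changed with IL-4c for 64 genes, 47 with a positive and 17 with a negative difference of differences. Of the positive ones 39 were called lowered by IL-4c in WT, and of the negative ones 13 were called raised. For these genes the IL-4c response was smaller in KO than in WT, or turned. That pattern is in part built in, as the WT arrays enter the interaction and the WT response with opposite signs. Over all 11634 genes, IL-4c in WT lowered 2228 and raised 2560 by the same threshold. The naive and IL-4c arrays were also separate sorts. Plac8 (4.92 ± 0.72, adjusted p = 0.0041), Tnxb (2.64), Hcar2 (2.45), Neurl3 (2.45), Hgf (2.24) and Csf3r (1.92) were positive, as were the immediate early genes Dusp1 (1.33), Ier3 (1.33), Jun (1.30) and Zfp36 (1.15). Ly6a2 (-4.20), Timd2 (-2.97), Mall (-2.72), Parm1 (-2.19) and Cd300lf (-1.48) were negative. The S phase list had a median of -0.625, with 1 gene called and 15 adjusted over the list alone (camera adjusted p = 8.29e-21; adjusted p = 0.207 with an estimated correlation). The count was 20 without IL-4c WT replicate 2, 33 without IL-4c KO replicate 1, 37 without naive WT replicate 2, 124 without IL-4c KO replicate 2, and 109 with an intensity trend and robust variance.

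Between the 2 resident populations of WT mice, LPM had higher Prg4 (8.55 ± 0.12, adjusted p = 1e-16), Cxcl13 (8.38), Alox15 (8.32), Saa3 (8.16), the complement receptor Vsig4 (8.15), Serpinb2 (7.93), Itgam (7.71) and C1qc (7.49), and AM had higher Atp6v0d2 (-8.51), Fabp1 (-8.48), Sh2d1b1 (-7.84), Plet1 (-7.64), Car4 (-6.94), Itgax (-6.81), Ctsk (-6.74) and Krt19 (-6.53). The LPM identity list was higher in LPM in 24 of 25 genes (median 6.078) and the AM identity list lower in 24 of 27 (median -4.455), at adjusted p = 9.81e-05 and 0.0077 with an estimated correlation. Gata6, the LPM transcription factor, was higher in LPM (4.31) and Bhlhe41 higher in AM (-4.32), as was Bhlhe40 (-1.13, adjusted p = 5.7e-05). MHC class II genes were lower in LPM in 7 of 8 (median -1.279; adjusted p = 0.246 with an estimated correlation). In all, 4452 genes passed, 2468 higher in LPM and 1984 higher in AM, or 2103 and 2482 with arrays centred on their medians. Many of the named genes lay below the array median in the lower cell type (LPM Fabp1 2.46 to 2.88 and Atp6v0d2 3.47 to 3.97, AM Cxcl13 3.13 and 3.33), so the size and order of these differences are limited by background. Cell type, tissue and preparation cannot be told apart here.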

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

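The interactions, list tests and left-out arrays of the first 2 paragraphs were planned, and the tests of explanations in the last 3 were chosen after the result was seen. What flagged their results is a tested difference between groups in the same KO minus WT contrast.

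Between naive and IL-4c LPM the KO effect differed for 64 genes. Positive differences of differences were those of Plac8 (4.92), Tnxb (2.64), Hcar2 (2.45), Neurl3 (2.45), Hgf (2.24), Csf3r (1.92), Dusp1 (1.33), Ier3 (1.33), Jun (1.30) and Zfp36 (1.15), and negative ones those of Cd300lf (-1.48), Parm1 (-2.19), Mall (-2.72), Timd2 (-2.97) and Ly6a2 (-4.20). Of the gene lists 11 differed by camera at the preset correlation, and 0 did with an estimated one. Their medians were -0.62 (S phase), -0.58 (G2/M), -0.25 (ribosome biogenesis), 0.18 (LPM identity), 0.28 (Maf-associated), 0.55 (LXR targets), 0.36 (interferon-stimulated), 0.39 (complement and phagocytic receptors), 0.31 (immediate early), 0.24 (neutrophil markers) and -0.48 (eosinophil markers). Without IL-4c WT replicate 2 the count was 20.

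Between naive LPM and AM the KO effect differed for 29 genes. Those named are Stab1 (3.76), Tlr1 (1.97), Rcn3 (1.81), H2-Eb1 (1.67), Tmc3 (1.60), Arg1 (1.58), H2-Ab1 (1.18), H2-Oa (1.05), Cd93 (-1.92), Stard13 (-1.98), Csf3r (-2.13), Lrg1 (-2.28) and Pglyrp1 (-2.51). Of the lists 5 differed at the preset correlation and 0 with an estimated one, with medians of -0.32 (LPM identity), 0.45 (Maf-associated), 0.99 (MHC class II), -0.44 (immediate early) and 0.39 (T and NK cell markers). Without AM KO replicate 2 the count was 9.

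The lower cell cycle signal of IL-4c KO LPM was weighed against 2 technical causes. A smaller response of all IL-4c-responsive genes was not excluded as the cause, in part or whole. The median ratio of KO to WT response was 0.84 over 976 other responsive genes. It was 0.90 (bootstrap interval 0.86 to 0.93) over the 560 raised by IL-4c, as the cell cycle genes are, and 0.80 over the 416 lowered. Over 66 cell cycle genes it was 0.67 (bootstrap interval 0.64 to 0.70, genes not being independent). But the KO response was taken against the naive KO arrays, of which replicate 3 had a mean cell cycle signal of 6.08, against 5.52 and 5.5 on the others. That array raises the baseline of the cell cycle genes and so lowers their ratio, and the ratio without it was not computed. A single WT array was not excluded as part of the cause. The median over both lists was -0.84 without WT replicate 1 and -0.52 without WT replicate 2, but each value rests on 1 WT array. Both KO arrays, with a mean cell cycle signal of 6.96 and 7, lay below both WT arrays, at 7.49 and 7.8. Replicates could differ on this measure too, as at 6.53 and 7.02 on the LysM arrays. A cause in genotype would also lower these genes on the second mutant: the arrays labelled Bhlhe40LysM had a median of -0.92, though against the same WT arrays.

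The higher Plac8, Ccl2, Ccl7 and Maf-associated genes of IL-4c KO LPM may reflect other cells in the sort. Over 16 MHC class II genes and markers of small peritoneal macrophages, monocytes and dendritic cells other than Plac8 the median difference was 0.05. Many of these are high in WT LPM already, so a small share of such cells would be hidden and the test cannot tell. Over 25 LPM identity genes it was 0.06 (bootstrap interval -0.40 to 0.19), which cannot tell whether LPM were fewer. No biological explanation was tested for this pattern.

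The arrays labelled Bhlhe40LysM keep the Bhlhe40 signal of WT. Cells without a working deletion would not carry the naive KO changes. Over the 219 genes called in naive LPM, the difference from WT was signed by the naive direction. Its median was 0.14 and 0.17 for the 2 LysM arrays against WT replicate 1, and 0.27 for each against replicate 2. The naive sign was kept by 160 genes (73.1%), against 174 (79.5%) for KO. On the LysM arrays it was kept by 59 of the 62 higher genes and 101 of the 157 lower ones, where 5 were called the opposite way. All these values use the same 2 WT arrays, and a shift of those arrays would move both mutants alike. Cells without a working deletion were therefore not excluded. Whether all 4 mutant arrays hold constitutive KO cells stays open. Bhlhe40 differed by -0.83 between the 2 pairs (95% interval -1.24 to -0.43, adjusted p = 0.18), but that difference only restates the pattern. KO minus LysM, Lyz1, the neighbour of the gene that carries Cre, differed by -1.91 (95% interval -2.75 to -1.07, adjusted p = 0.13). Lyz2, which carries Cre, differed by 0.05 (adjusted p = 0.96). Probes outside the deleted part, or labels exchanged between the 2 pairs, also remain possible and were not tested. Exchanged labels would put constitutive KO cells at the WT level of Bhlhe40, though the KO arrays of AM and naive LPM read below WT.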

How the results depend on the processing

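No test here was chosen after the result was seen, and the alternatives were planned before the data were examined. Of 172 named gene values, none turned direction under normalization, filter, probe set or variance alternatives, though many were named for a large change. Of these values 31 lost their call with only the compared arrays and 8 with an intensity trend and robust variance. Of 81 list calls 78 were lost with an estimated correlation. Signal over background limits the 8304 dim genes, which were not tested. For the values below the cause was not tested, beyond fewer arrays in a fit giving less power.

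Called genes moved by over 1.5 times as follows. Array weights gave 419 in naive LPM (219 in the fit used), 61 in the cell type interaction (29) and 1 in KO against LysM (2). Only the compared arrays gave 117 in IL-4c KO (422), 150 in LysM (1009), 0 in KO against LysM and 62 in the cell type interaction. An intensity trend with robust variance gave 8 in KO against LysM and 109 in the IL-4c interaction (64), and the mean of a gene's probe sets gave 45 in the cell type interaction. Leaving out 1 array gave 8 to 19 in AM, 75 to 163 in naive LPM, 84 to 418 in IL-4c KO, 240 to 1193 in LysM, 1 to 111 in KO against LysM, 2787 to 4081 for IL-4c in KO, 20 to 124 in the IL-4c interaction and 9 to 57 in the cell type interaction. Bhlhe40 in LysM against WT ran from -0.20 to 0.02, the latter without WT replicate 2. In KO against LysM the list G2/M and mitosis ran from camera adjusted p = 2.7e-20 (without LysM replicate 2) to 0.73 and oxidative phosphorylation from 1.1e-06 to 0.99, both turning direction without LysM replicate 1.

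The labels do not say that replicate numbers pair the arrays, so the block is given only here: deviations of same-numbered arrays correlated at -0.071 in AM, 0.066, 0.009 and -0.139 in naive LPM, and 0.115 to 0.21 in IL-4c LPM, where 2 arrays per group give each pair of groups 1 correlation. Not every naive array correlated best with its own number. With a replicate block the counts were 14, 177, 465, 1028, 12, 4525, 4038, 96, 26 and 4253, in the order AM, naive LPM, IL-4c KO, LysM, KO against LysM, IL-4c in WT and KO, IL-4c interaction, cell type interaction and LPM against AM.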

Other observations

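The histone test in this part was chosen after the result was seen, while the splits of the naive arrays were planned before their result.

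Histone genes, chosen by symbol and mostly of the kind transcribed in S phase, may follow the cell cycle genes. The choice by symbol also took in others, such as H1f7 and H2bu1-ps. Of 28 tested, 8 were lower in IL-4c KO than WT LPM (median -0.65; camera p = 1.3e-10; p = 0.028 with an estimated correlation) and 17 in the arrays labelled Bhlhe40LysM (median -0.98), while in naive LPM the median was -0.19 (camera p = 0.069). In IL-4c LPM the histone genes were thus lower along with the cell cycle lists. In AM they did not move together. There the histone median was -0.21 with camera p = 0.00016 (p = 0.16 with an estimated correlation), while the cell cycle medians were 0.083 and 0.014. IL-4c itself raised 23 of the 28 in WT.

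For naive LPM, 10 splits of the 6 arrays into 3 and 3 exist, too few for a share under 0.05; 1 of them, the real one, gave 219 genes, and the highest of the others gave 0.

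Naive KO replicate 3 had a mean cell cycle signal of 6.08, against 5.52 and 5.5 on the other 2 arrays, a Mki67 signal of 7.41 against 6.48 and 6.27, and an array weight of 0.59. Csf3r read 7.46 and 7.9 in AM KO against 6.31 and 6.48 in WT. Lyz2, the gene that carries Cre in LysM-Cre mice, differed by 0.40 between the arrays labelled Bhlhe40LysM and WT (adjusted p = 0.22), its neighbour Lyz1 by 1.63 (adjusted p = 0.018), and Lyz2 fell by 2.26 with IL-4c in WT. Within 10 Mb of Bhlhe40, 4 of 64 tested genes (6.25%) were called in naive LPM, against 1.85% elsewhere (odds ratio 3.53, Fisher exact p = 0.032, 0.16 adjusted over 5 comparisons). In IL-4c KO and on the arrays labelled Bhlhe40LysM the odds ratios were 1.79 and 1.09 (exact p = 0.29 and 0.82), and AM and KO against LysM had 0 called there. Xist read at most 4.38, below the lowest array median of 4.79, and the Y-linked genes Kdm5d, Eif2s3y and Uty read 5.5 to 7.75, on all 16 arrays.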
